A study of Rattus norvegicus with 8 samples.

How the data were processed

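Hypothalamic RNA of 8 lactating Wistar rats was measured on postpartum day 7, with 4 control dams and 4 dams exposed to TCDD, per the labels and the series' design text. TCDD is the reference dioxin and a ligand of the aryl hydrocarbon receptor (AhR). The dose, route and time of exposure are not given in the sources used here. Per the labels' protocols, the tissue went into RNAlater, total RNA was extracted with RNeasy columns, and Cy3-labelled cRNA was made with an Agilent low-input amplification kit. Each sample was hybridised to 1 Agilent Whole Rat Genome array in 1 colour.

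The deposited scanner files hold spot intensities on a linear scale, made with Agilent Feature Extraction 10.7.1.1 per the file headers. Per the file headers, the processed signal of a spot is background-subtracted and corrected for spatial trends within its array, and a spot not above background carries a surrogate value. The authors also deposited a value table of intensities on a linear scale. All 8 of its columns have a median of 65.1 and the same set of values, as quantile normalization gives, and its log2 values correlated with the scanner values at r of 0.999 or more across probes. Its centring beyond that is not stated in the sources used here, and it served as an alternative. Probe coordinates are those of the file headers' design, on the rat build rn4. No genome or gene annotation of that build was used, so exon and UTR positions are not given.

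The main values were log2 of the processed signal minus the 75th percentile of the array's non-control spots. The 1377 control spots were left out. The remaining 42877 spots belong to 30367 probes, and spots of the same probe (1390 probes had several) were averaged. Spots that the scanner software marked as outliers on an array were left out of that array's average. A probe entered the test if it was well above background on all 4 arrays of at least 1 group, which 19102 probes were. A gene name was represented by its probe with the highest mean signal, and 2302 genes had several such probes. This left 16574 genes. The design holds 26269 gene names, and 10351 probes lack a name of the gene symbol kind. Accessions matched 18394 probes to a table of current rat symbols (assembly GRCr8, used for names alone). Old symbols and accessions together gave a current symbol for 21395 probes, and it differed from the array's name for 2417. Array names are used in the text.

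Group differences were tested with limma 3.58.1 (lmFit and eBayes, 2-sided, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. No fold cut-off was set. A log2 fold change is TCDD minus control, with its standard error (SE). A gene that was dim, or not well above background, on some arrays may have a bound instead of a fold. It sets the brighter group's mean against the other group's mean. Each dim array of that other group is first raised to its lowest signal well above background. Dim arrays of the brighter group keep their background value, and the bound holds on the main scale alone. In all, 33 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 measured members, and again with an estimated correlation. Array measures and list scores (the mean log2 signal of the members) were tested with a 2-sided exact permutation test over the 70 assignments of the arrays, whose smallest p is 0.0286. The alternatives concerned background correction (normexp with an offset of 50), scaling, the authors' table, the filter, the handling of several probes, the variance model, array weights, the replicate number as a block, and each array left out in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

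The test, the lists, the alternatives and the rule for named genes were chosen before the data were examined, except where stated. The rule named 20 hormone, receptor and dioxin-response genes whatever their test. It added the 12 largest rises and the 12 largest falls past the threshold whose groups did not overlap, leaving out names that are accessions or locus numbers. It filled each direction up to 5 with the genes of smallest p, which are said not to pass. It also named list members past the gene test, of which there were 0 in limma. The passing probes with no symbol, the pituitary genes other than Prl, and the example members of the lists were chosen after their values were seen.

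The gene test was checked on simulated data for 16574 genes of this comparison, with 200 genes changed. It recovered 48.6% of genes changed by 0.5, 84.3% of those changed by 1 and 93.3% of those changed by 2 on the log2 scale, with 7 false calls. The adjusted threshold is easier to reach with 200 changed genes than with few. In the real comparison 3 passed, so these shares can overstate recovery there. The list test called 3 of 3 shifted lists of 20 genes and 0 of the others, at a shift of 0.3. The simulated genes varied independently of each other, so this check cannot show how often the list test calls lists of correlated genes falsely. The 4 control arrays lay on 1 slide and the 4 TCDD arrays on another, scanned separately, so slide and group cannot be told apart. The replicate number equals the position on the slide. The number of arrays limits the precision.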

Results

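The series asks how dioxin affects hypothalamic mRNAs of rat mothers, and its design implies a single comparison, of 4 TCDD-exposed dams with 4 control dams on postpartum day 7. Between 69.3% and 73.7% of the probes were well above background on an array. The 75th percentile of the processed signal ranged from 474 to 699, and the correlation between arrays across probes ranged from 0.988 to 0.996. Repeated probes varied most on the position 1 arrays, with a coefficient of variation of 5.43% on control replicate 1 and 5.15% on TCDD replicate 1, against 3.46% to 4.04% on the others. Among 6 measures of array quality compared by exact permutation, a single one that differs cannot reach an adjusted p below 0.171, so this test excludes no difference. The slope of the spike-in controls was higher on every TCDD array than on any control array, at 1.01 ± 0.00703 in control and 1.02 ± 0.00541 in TCDD arrays (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.171). All other measures gave exact p-values of 0.4 or more.

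Few single genes passed the test between the hypothalamus of TCDD-exposed and control dams, which lay on separate slides. Wdr96, now named Cfap43 and required for the beating of motile cilia and flagella, rose 6.61-fold in TCDD dams. Its log2 signal was -3.66 ± 0.30 in control and -0.94 ± 0.40 in TCDD dams (SD, n = 4 each), a log2 fold change of 2.73 (SE 0.22, limma adjusted p = 0.0217). The gene RGD1565030 rose by 1.12 on the log2 scale (SE 0.11, adjusted p = 0.0324). Probe A_64_P150579, which carries no gene name, rose by 0.84 (SE 0.079, adjusted p = 0.0324). All 4 TCDD values of these 3 features lay above all 4 control values.

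The Wdr96 probe lies on chromosome 1 at 253107405 to 253107464 (rn4). A second Wdr96 probe showed a log2 fold change of 0.03, and the mean of both probes gave 1.38 (adjusted p = 0.0325). RGD1565030 lies on chromosome 17 at 34472160 to 34472218, and A_64_P150579 on chromosome 11 at 5301556 to 5301615. With normexp background correction the change of Wdr96 was 1.80 (adjusted p = 0.00514), that of RGD1565030 was 0.55 (adjusted p = 0.0393) and that of A_64_P150579 was 0.36 (adjusted p = 0.323). Over 13 alternatives the adjusted p ran from 0.00314 to 0.181 for Wdr96, from 0.0216 to 0.214 for RGD1565030 and from 0.0286 to 0.323 for A_64_P150579. The last is among 1890 tested probes with no gene name, which as a class lay 0.12 higher relative to named probes in TCDD arrays, with no overlap of the groups (SE 0.024, exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give).

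Of the 16574 genes tested, these 3 were higher and 0 lower in TCDD dams with limma, and 1822 stood at an unadjusted p under 0.05 (1202 higher, 620 lower), where chance gives about 1 gene in 20. Among the 11464 genes with a symbol, 3.33% were higher and 4.35% lower at that level, and among the 1890 probes with no gene name 472 were higher and 1.64% lower. The groups did not overlap in 1212 genes, or 7.31%, against 2.86% by chance. The median absolute log2 fold change was 0.076, and 75 genes reached 1. Without control replicate 1 the count was 1 and without control replicate 3 it was 7. It was 0 without control replicate 2, control replicate 4, TCDD replicate 2, TCDD replicate 3 or TCDD replicate 4, with 1423, 2119, 1801, 1429 and 1650 genes at an unadjusted p under 0.05.

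Genes next in rank did not pass. Higher in TCDD dams were Pgc, the precursor of a gastric protease, at 0.51 (SE 0.062), the olfactory receptor Olr1414 at 0.69 (SE 0.090), cardiac actin Actc1 at 0.46 (SE 0.063) and the granulocyte growth factor Csf3 at 0.39 (SE 0.056). Each had an adjusted p of 0.0575. With normexp, Olr1414 stood at 0.18 and Csf3 at 0.023 (adjusted p = 0.818 and 0.977). Lower were the RNA helicase Dhx9 at -0.43 (SE 0.061, adjusted p = 0.0575), the pseudokinase Trib1 at -0.44 (SE 0.079, adjusted p = 0.108) and the microtubule-binding protein Eml1 at -0.50 (SE 0.095, adjusted p = 0.118). The pancreatic protease Cpa1 stood at -1.10 (SE 0.21, adjusted p = 0.120). With normexp, Trib1 stood at -0.25 and Cpa1 at -0.33 (adjusted p = 0.662 and 0.401). Without TCDD replicate 1 Cpa1 passed, at -1.34 (adjusted p = 0.00186, the smallest over 13 alternatives, with 0.401 the largest). Sdr9c7 was well above background on 4 control and 0 TCDD arrays. On the main scale alone, its bound was 1.28-fold higher in control dams (limma adjusted p = 0.110, log2 fold change -0.46, and -0.26 with normexp).

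Hormone and receptor genes of the hypothalamus did not pass the test, whether bright as Oxt and Avp or dim as Kiss1. Oxt, which encodes oxytocin, had a log2 signal of 6.58 ± 0.31 in control and 6.34 ± 0.18 in TCDD dams (SD, n = 4 each; log2 fold change -0.24, SE 0.16, adjusted p = 0.654). Avp, which encodes vasopressin, gave 6.93 ± 0.54 and 6.37 ± 0.43 (log2 fold change -0.56, SE 0.30, adjusted p = 0.559). The log2 fold change of Th, the rate-limiting enzyme of dopamine synthesis, was -0.44 (SE 0.25, adjusted p = 0.596). For the appetite genes it was 0.01 for Pomc, -0.19 for Npy and -0.29 for Agrp, with SEs of 0.38, 0.24 and 0.34. For the reproductive peptides it was 0.21 for Gnrh1 (SE 0.49) and -0.27 for Kiss1 (SE 0.23). Among the releasing hormones, Trh stood at 0.27 (SE 0.12, adjusted p = 0.439) and Crh at 0.17 (SE 0.25). Of the hormone receptors, the prolactin receptor Prlr stood at -0.04 (SE 0.15) and the progesterone receptor Pgr at -0.12 (SE 0.083). Adjusted p-values of Pomc, Npy, Agrp, Gnrh1, Kiss1, Crh, Prlr and Pgr lay between 0.660 and 0.996. The sign of Pomc, Npy, Gnrh1, Crh and Prlr turned when single arrays were left out. The other values ranged, over arrays left out, from -0.31 to -0.087 for Oxt, -0.75 to -0.33 for Avp, -0.62 to -0.26 for Th, -0.49 to -0.075 for Kiss1, -0.53 to -0.017 for Agrp, 0.21 to 0.38 for Trh and -0.17 to -0.054 for Pgr, with adjusted p-values of 0.210 or more.

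**Figure D1:**
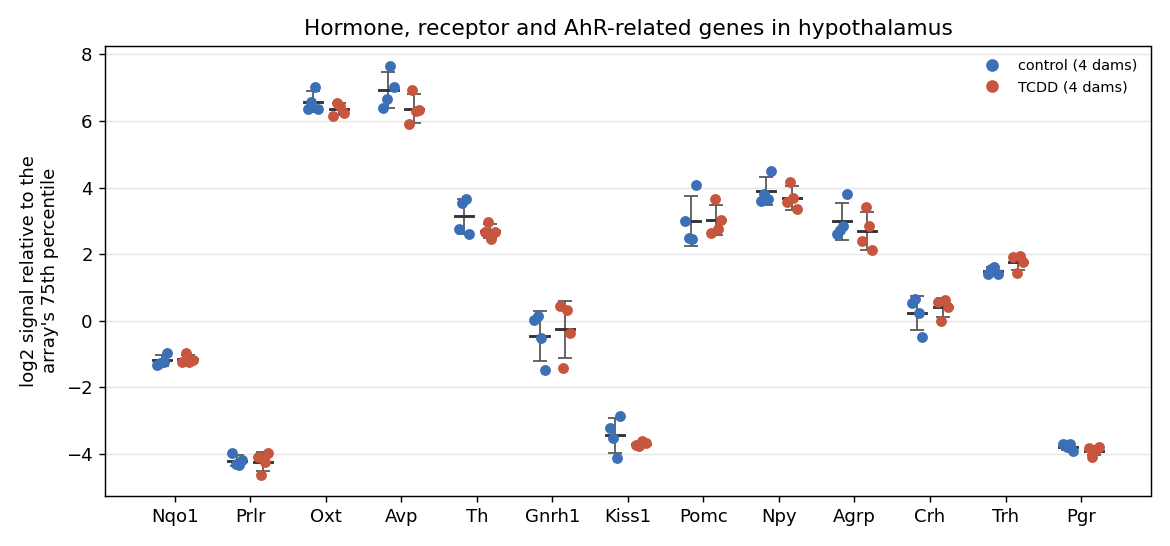
Log2 signal relative to the array's 75th percentile (y axis) for 13 hormone, receptor and AhR-related genes (x axis), 1 point per dam, with control in blue and TCDD in red. Lines show the mean and bars the SD (n = 4 each), and the groups overlap in every gene shown.

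Several genes of the AhR pathway were at or near background. Cyp1a1, the cytochrome P450 most used as a marker of AhR activation, was well above background on 0 control arrays and on TCDD replicates 2 and 4, at log2 signals of -4.86 and -5.03, so no fold is given. All 4 TCDD values lay above all 4 control values (exact permutation p = 0.0286, the smallest possible). Limma without the filter gave an adjusted p of 0.593. Both tests rest on background values on the dim arrays. Cyp1b1, Ahrr and the oestrogen receptor gene Esr1 were not well above background on any array, and Ahr itself was so on 1 control and 1 TCDD array. Cyp1a2, outside the rule for named genes, was also not well above background on any array. Its highest signals were on TCDD replicates 2 and 4, at -6.43 and -6.56 (limma without the filter, adjusted p = 0.588, and exact permutation p = 0.0857). No probe carries the name Tiparp. Nqo1, a quinone reductase induced through AhR and NRF2, had a log2 signal of -1.19 ± 0.16 in control and -1.16 ± 0.13 in TCDD dams (SD, n = 4 each; log2 fold change 0.03, SE 0.097, adjusted p = 0.947; -0.03 with normexp). In the AhR target battery, 6 of 14 genes were measured, Cyp1a1 and Cyp1a2 not among them. Of these 3 were higher and 3 lower, and the list was not called (camera adjusted p = 0.890). Its largest values were -0.22 for Cyp2s1, 0.20 for Aldh3a1 and -0.17 for Xdh.

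Prl, which encodes prolactin, was well above background on 1 control and 3 TCDD arrays. Its log2 signal was 0.42 on control replicate 2 and 2.09, 2.53 and 2.57 on TCDD replicates 2, 3 and 4. On the main scale the bound for Prl was 22.9-fold, with the TCDD mean the higher. TCDD replicate 1 entered it at its background value, so this bound is not a strict minimum. The difference did not pass (limma without the filter, adjusted p = 0.651, and exact permutation p = 0.0571). The bound was 65.7-fold without control replicate 2, 93.6-fold without TCDD replicate 1, and 13.7-fold to 16.4-fold without each of the other arrays. The fitted log2 fold change, 5.85 without the filter and 3.35 with normexp, rests on background values of the dim arrays and is no estimate of a fold (adjusted p from 0.487 to 0.857 over the alternatives). The growth hormone gene Gh1 was above background on the same 4 arrays, at -3.66 on control replicate 2 and at -2.54, -2.08 and -1.63 on those TCDD arrays. The bound for Gh1 was 3.34-fold on the main scale, again with TCDD replicate 1 at its background value (limma without the filter, adjusted p = 0.672). That bound was 4.74-fold without control replicate 2, 8.49-fold without TCDD replicate 1, and 2.21-fold to 3.04-fold without each of the others. Its fitted values, 3.43 and 1.08 with normexp, rest on background values in the same way (adjusted p from 0.433 to 0.857). Cga and Tshb, which encode subunits of thyrotropin, were brightest on a set of arrays that only partly overlapped with these. Cga reached 5.59 on control replicate 4, 5.90 on TCDD replicate 2 and 5.29 on TCDD replicate 4, against 1.69 or less on the other arrays.

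**Figure D2:**
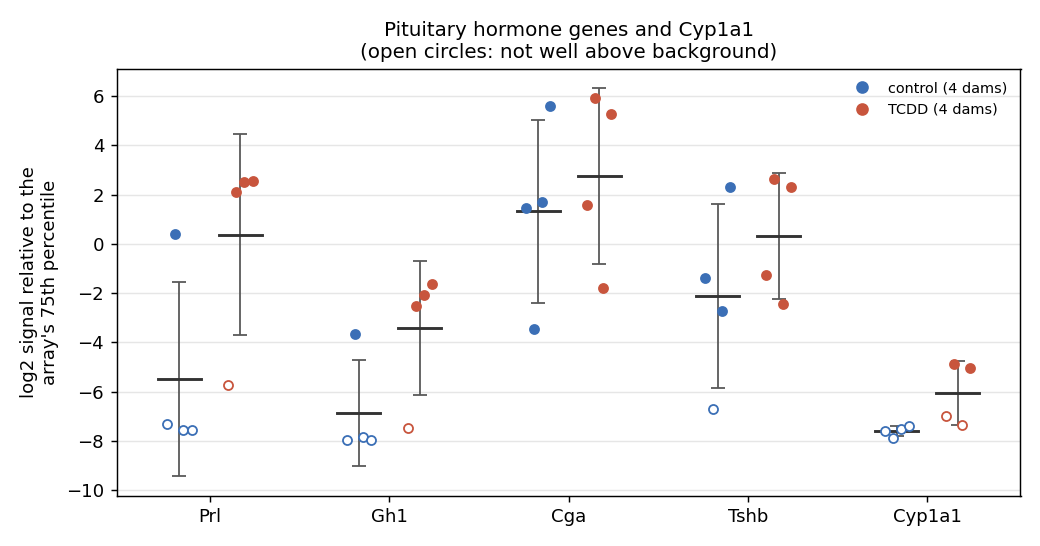
Log2 signal relative to the array's 75th percentile (y axis) for 4 pituitary hormone genes and Cyp1a1 (x axis), 1 point per dam, with control in blue and TCDD in red. Open circles are not well above background, and lines and bars show the mean and SD of all 4 arrays. Prl and Gh1 are both well above background on 1 control and 3 TCDD arrays.

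Of 33 gene lists, 4 were called by camera, and 0 of these with an estimated correlation (smallest adjusted p = 0.826). Of the 496 genes measured in the lists, 0 passed limma over all genes. Immediate early genes, which neurons switch on soon after stimulation, were higher in TCDD dams (camera adjusted p = 0.00143; adjusted p = 0.826 with an estimated correlation). Of 16 measured members, 14 were higher and 2 lower, with a median log2 fold change of 0.29. At an unadjusted p under 0.05, 6 members were higher and 1 lower, and 0 passed limma, over all genes or adjusted over the list alone. Examples were Nr4a3 at 0.41, Egr1 at 0.38, Btg2 at 0.35 and Fosl2 at -0.33, with Nr4a3 at 0.26 and Fosl2 at -0.16 under normexp. A second Egr1 probe stood at 0.17, and the mean of both probes gave 0.28. The list scores overlapped, with a group difference of 0.25 (exact permutation p = 0.0857). Without TCDD replicate 1 the adjusted p was 0.0537, the largest over the arrays left out, with 5.97e-06 the smallest. Without both position 1 arrays, chosen after seeing the data, it was 0.0681.

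Interferon and MHC class I genes, the antiviral and antigen-presenting response, were lower in TCDD dams (camera adjusted p = 0.00261; adjusted p = 0.826 with an estimated correlation). Of 19 measured members, 14 were lower and 5 higher, and the median was -0.17. At an unadjusted p under 0.05, 4 were lower and 0 higher, and 0 passed limma over all genes or adjusted over the list alone. These 4 were Isg15 at -0.79 (SE 0.30), Oas1a at -0.73 (SE 0.24), Usp18 at -0.71 (SE 0.22) and Irf9 at -0.23 (SE 0.098). With normexp, Oas1a stood at -0.35, Usp18 at -0.40 and Irf9 at -0.13. The score difference was -0.24 (exact permutation p = 0.114). The adjusted p was 0.120 without control replicate 4 and 0.109 without TCDD replicate 3, in a range from 2.45e-05 to 0.120 over the arrays left out.

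Red blood cell genes were higher in TCDD dams (camera adjusted p = 0.00343; adjusted p = 0.826 with an estimated correlation), with a median of 0.88. All 5 measured members were higher, 4 at an unadjusted p under 0.05, and 0 passed limma over all genes or adjusted over the list alone. The beta globin genes Hbb and Hbb-b1 stood at 0.88 (SE 0.31) and 1.07 (SE 0.43), the alpha globin gene Hba-a2 at 0.67 (SE 0.29), the haem synthesis enzyme Alas2 at 1.47 (SE 0.57) and the globin chaperone Ahsp at 0.72 (SE 0.42). The score difference was 0.96 (exact permutation p = 0.114), and control replicate 4, at 1.20, lay within the range of the TCDD scores from 0.40 to 1.47. The red blood cell call held without each array (adjusted p up to 0.0272).

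NRF2 and metal response genes, the antioxidant and metal-binding defence, were lower in TCDD dams at the edge of the threshold (camera adjusted p = 0.0481; adjusted p = 0.826 with an estimated correlation). Of 16 measured members, 11 were lower and 5 higher, and the median was -0.13. At an unadjusted p under 0.05, 5 were lower. Over all genes 0 passed limma, and adjusted over the list alone 1 did, the peroxiredoxin Prdx1 at -0.29 (SE 0.058, adjusted p = 0.0155). Catalase (Cat) stood at -0.14, Srxn1 at -0.19, Gclc at -0.14 and Mt3 at -0.18. The call ended without control replicate 4 (adjusted p = 0.308), TCDD replicate 1 (0.0975), TCDD replicate 3 (0.109) or TCDD replicate 4 (0.261), the smallest over the arrays left out being 0.00178. It also ended with quantile normalization (0.0948), normexp (0.0588), the authors' value table (0.0945), the mean of probes (0.0953) and ranks (0.103), and, chosen after seeing the data, without position 1 (0.0681) or unnamed probes (0.0683).

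**Figure D3:**
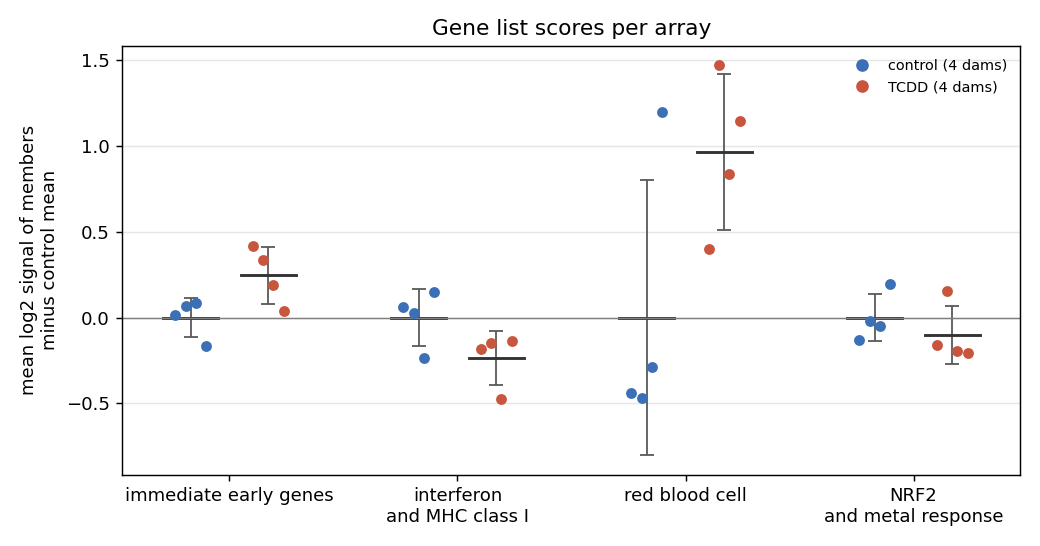
Mean log2 signal of the measured members of the 4 called lists minus the control mean (y axis), by list (x axis), 1 point per dam, with control in blue and TCDD in red. Lines show the mean and bars the SD (n = 4 each), and the groups overlap in every list.

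The lists closest to lactation and hypothalamic output were not called by camera. Adjusted p-values were 0.196 for the GnRH and kisspeptin axis (13 measured, median -0.13), 0.279 for dopamine and catecholamine genes (12 measured, median -0.16), 0.718 for prolactin-STAT5 signalling (11 measured, median -0.04) and 0.935 for maternal hormones and receptors (14 measured, median -0.02, mean 0.01). They were 0.982 for hypophysiotropic hormones (14 measured, median -0.07), feeding and energy balance (20 measured, median 0.02, tested as lower) and stress and glucocorticoid genes (12 measured, median -0.07), and 0.902 for thyroid hormone genes (13 measured, median -0.04). In these lists 0 genes passed limma over all genes. Adjusted over the list alone 1 did, the vesicular monoamine transporter Slc18a2 among dopamine genes, at -0.34 (SE 0.086, adjusted p = 0.0462).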

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

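The tests of other splits of the arrays and of the receptor class were chosen before their results were seen, although 1 receptor gene, Olr1414, had been seen; the tests of GC content, slide position, slide, pituitary carry-over, exposure alone and blood were chosen only after the result was seen.

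For Prl and Gh1, control replicate 2 was the highest control, with a gap to the next array of 0.968 (Prl) and 0.970 (Gh1) of the group's range, and TCDD replicate 1 was the lowest TCDD array for Prl (0.943) and Gh1 (0.843). Both genes lie outside the gene test, with 3 TCDD arrays and 1 control above background. Prl of control replicate 2 lay at least 5.99 above the other controls on the log2 scale, these being at background, which argues against exposure as the only source. Prl and Gh1 were both or neither above background on 8 of 8 arrays, but this restates what prompted the test and 0 of 13 other pituitary genes followed the same arrays, so pituitary tissue or RNA carried over at dissection stays a hypothesis that this count does not decide. Against a uniform piece of pituitary, Cga and Tshb were brightest on control replicate 4 and TCDD replicates 2 and 4, and Pou1f1, Fshb and Ghrhr were not well above background anywhere. Pomc, which the hypothalamus also expresses, was highest on control replicate 4 (4.07) and TCDD replicate 2 (3.65). The hypothalamic appetite genes Npy (4.50 and 4.18) and Agrp (3.81 and 3.41) were highest on the same arrays, so Pomc does not bear on pituitary here. Why 3 of 4 TCDD arrays carried the Prl and Gh1 signal stays open, an effect of exposure included.

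Red blood cell genes were flagged for control replicate 4, which was the highest control for Alas2 (0.872), Hbb-b1 (0.836) and the list score (0.893). Control replicate 4 was the highest control in 5 of 5 measured members, and TCDD replicate 1 the lowest TCDD array in 5 of 5. This count repeats in part the values that prompted it, so it does not decide whether blood left in the tissue is the source. Blood left in the tissue cannot be told apart here from a higher blood content or more immature red cells in TCDD dams, since all of these move the same 5 genes.

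Probes with no gene name were higher in TCDD arrays: 472 of 1890 were higher at an unadjusted p under 0.05, against 382 of 11464 named ones (3.33%). Matching for GC content and brightness left a group difference of 0.119 on the log2 scale (0.119 before), which argues against these as the cause; that the TCDD array was higher at each slide position, by 0.0624 or more, follows from groups that did not overlap and decides nothing about position. Smell, pheromone and trace amine receptor genes, which brain hardly expresses, shifted by 0.281 (48 genes, SE 0.074, exact permutation p = 0.0286). This shift was not matched for brightness, and a probe well above background in the TCDD group alone could enter it. With normexp the receptor Olr1414 went from 0.69 to 0.18. Signal from DNA or unspecific binding may contribute, but this shift does not decide it. The slide or the processing run cannot be told apart from exposure, since each slide held 1 group, and the shift ranged over 0.0990 within the control slide and 0.0428 within the TCDD slide. An effect of exposure on unannotated transcripts was not tested and stays open.

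Other single arrays that stood apart are given as the gap to the nearest array over the range of the group, with 19 of 170 groups examined (11.2%) standing apart where chance gives about 1 in 20; TCDD replicate 2 and control replicate 4 account for 5 each. For single genes, these were Pgc (control replicate 3 highest, 0.875), Olr1414 (control replicate 4 highest, 0.941) and Cpa1 (TCDD replicate 1 highest, 0.852). For called lists, they were the interferon and MHC class I score (TCDD replicate 3 lowest, 0.850) and the NRF2 and metal response score (TCDD replicate 2 highest, 0.873). The meninges and fibroblast score stood apart in both groups (control replicate 1 lowest, 0.856, and TCDD replicate 2 highest, 0.898). TCDD replicate 2 was also highest for choroid plexus (0.839) and astrocyte genes (0.869) and lowest for hypothalamic transcription factors (0.857). Control replicate 4 was highest in the AhR target battery (0.879), and TCDD replicate 4 had the lowest median background (0.889).

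Cyp1a1 was above background on 2 TCDD arrays and no control, outside the gene test. It was among 81 such genes, against 104 above background on 2 control arrays and no TCDD array. Among 9695 genes outside the test, 16 were above background on 3 TCDD arrays and no control, of which 11 have no gene name, and 32 on 3 control arrays and no TCDD array.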

How the results depend on the processing

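The settings without position 1 and without unnamed probes were chosen only after the results were seen. The count of 3 changed genes was the same, within 1.5 times, with quantile or median scaling (3 each), the authors' table (4), the mean of probes, every probe or outlier spots kept (3 each), a fold cut-off or no unnamed probes (2 each). Without position 1 it was also 2, but 1 higher and 1 lower, with only 1 of the main 3 among them. It was 22 with normexp (1136 at an unadjusted p under 0.05, against 1822), 28 with the stricter filter (27 higher, 1 lower), 34 with a trended robust variance (33 higher, 1 lower), 96 with array weights (91 higher, 5 lower), 1 with no scaling (610 at an unadjusted p under 0.05, fewer than 1 gene in 20) and 0 with no filter, where 26269 genes were tested and limma gave 2012 at an unadjusted p under 0.05. Over arrays left out it ran from 0 (without control replicate 2 or 4, or TCDD replicate 2, 3 or 4) to 7 (without control replicate 3); without control replicate 1 it was 1. With the replicate block it was 0, with 2111 at an unadjusted p under 0.05 and an adjusted p of 0.125 for Wdr96, RGD1565030 and A_64_P150579 at unchanged fold changes; same-number arrays correlated at 0.228, -0.003, -0.046 and 0.104, not every array correlated best with its own number, and the numbers were not taken to pair the dams. Lists called numbered 4, 0 with an estimated correlation, 2 without position 1, and 2 (without TCDD replicate 1 or 3) to 7 (without TCDD replicate 2) over arrays left out; the block ended the NRF2 and metal response call (adjusted p = 0.0879, range 0.00178 to 0.826) and no other list call.

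Over 13 alternatives Wdr96 ranged from 1.38 to 2.92 and passed in 7, RGD1565030 from 0.55 to 1.19 in 5, and A_64_P150579 from 0.36 to 0.90 in 3. Of 44 genes, 6 changed sign, none of them past the threshold in the main test. Nqo1 was -0.030 with normexp and ranged from -0.035 to 0.11 over arrays left out, Prlr from -0.13 to 0.092, Gnrh1 from -0.13 to 0.60, Pomc from -0.20 to 0.37, Npy from -0.36 to 0.012 and Crh from -0.071 to 0.30. In all, gene values kept their sign and side of the threshold in 532 instances, fell short of it in 24 and newly passed in 1; list calls held in 52 and were lost in 20. The causes were not tested. The slide as a block was not run, as each slide held 1 group. Signal over background limits the test to genes above it in a whole group, leaving 9695 outside.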

Other observations

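The tests of other splits of the arrays were chosen before the data were examined; the comparison of a split with the meninges score was made only after the result was seen. The red blood cell list was the only marker list of a cell type or brain region that camera called. Of the other lists, the clock genes came nearest to a call (17 measured, 12 higher, median 0.07, camera adjusted p = 0.164). Smallest in unadjusted limma p were Hlf at 0.25 and Nr1d2 at 0.20, and the largest rise was that of RGD1566380 at 0.28. All 14 measured meninges and fibroblast genes were lower in TCDD dams (median -0.35, adjusted p = 0.246), but the scores varied widely within groups, from -1.01 to 0.44 in control and from -1.29 to 1.49 in TCDD dams. Cholesterol and fatty acid synthesis genes (23 measured, 17 higher, median 0.02) gave an adjusted p of 0.246. Adjusted p-values were 0.267 for thalamus (median 0.23), 0.306 for inflammatory cytokines (median -0.19) and 0.415 for each of cortex and hippocampus (median 0.05), anterior pituitary (median 0.12), GABA and glutamate transmission (median -0.03), oxidative phosphorylation (median -0.03) and microglia (median -0.05).

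They were 0.607 for oligodendrocyte and myelin (median -0.08), 0.636 for endothelium and pericyte (median 0.05), 0.904 for choroid plexus (median 0.01) and 0.935 for synapse and neuron (median -0.01). For astrocytes (median -0.0038), ependyma and tanycytes (median -0.05), hypothalamic transcription factors (median -0.0035), heat shock and unfolded protein genes (median 0.0047) and ribosomal proteins (median -0.00017) they were 0.982, and 0.902 for striatum and septum (median -0.00054). The camera direction was up for ependyma, hypothalamic transcription factors and striatum although the median was below 0, and the mean had the opposite sign to the median for choroid plexus, striatum and ribosomal proteins. In these lists 0 genes passed limma over all genes, and adjusted over the list alone 1 did in each of 2 lists, Emx1 of cortex and hippocampus at 0.22 (adjusted p = 0.0233) and Kcne2 of choroid plexus at 0.26 (adjusted p = 0.0162).

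Chance cannot be excluded for the number of changed genes. Of the 35 splits of the 8 arrays into 4 against 4, 5 gave 3 or more genes, the real one included. The highest other split gave 12. Whether that count exceeds what chance gives for the largest of many splits was not tested. The split set control replicate 1 and TCDD replicates 1, 3 and 4 against the rest. These same 4 arrays had the 4 lowest meninges and fibroblast scores (-1.01, -1.29, -1.10 and -1.01). A split by slide position, 1 and 2 against 3 and 4, gave 4 genes, near the 3 of the real split. The other splits by position, 1 and 3 against 2 and 4, and 1 and 4 against 2 and 3, gave 0 genes each. With position as a block, a fit of another form, the real comparison gave 0 (2111 at an unadjusted p under 0.05 in limma). At an unadjusted p under 0.05 the real split gave 1822 genes. As many or more came from 2 of the 35 splits, the real one included, and the highest other gave 2272. For gene lists, 28 of the 35 splits, the real one included, called 4 or more, and the highest other called 15. Chance cannot be excluded there either.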
